A study of Rattus norvegicus with 15 samples.

How the data were processed

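Small RNA sequencing libraries enriched for tRNA fragments were made from left ventricles of Sprague-Dawley rats, in 3 groups of 5 animals. The groups were untreated controls, rats with ischemia induced by isoproterenol, and rats kept on caloric restriction before the isoproterenol. Total RNA was pretreated with a commercial kit that removes base modifications which block reverse transcription, and amplified products of 134 to 160 bp, holding inserts of 14 to 40 nt, were taken from a gel, per the labels' protocols. Cutadapt and edgeR were named without versions or roles, per the submitters' processing notes. The aligner, the tRNA reference, the mismatch rule and the genome build are not given in the sources used here.

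The table deposited by the authors held CPM (reads per 1000000 reads of the library total) for 714 tRNA-derived small RNAs (tsRNAs) in 15 libraries, 1 column per rat. Each tsRNA name gives a class, the parent amino acid, the anticodon and a serial number, per the file headers. Of the names, 665 were tRNA-derived fragments (tRF) and 49 were tiRNAs (products of cleavage in the anticodon loop). They covered 20 amino acids and 46 isoacceptors. No sequence or position within the tRNA was used, so tsRNAs of nearly identical sequence from 1 isoacceptor cannot be separated here and are uncertain as single species. Marker microRNAs of other cell types, tsRNAs of selenocysteine tRNA and a list of mitochondrial parents as named by the authors were not analysed here.

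The deposited CPM values were whole multiples of 1 read in each library: 100% of the values were whole within a tolerance of 0.001 reads. This gave the library total by which the authors divided, from 106082 to 1128887 reads, so that 1 read was worth 0.886 to 9.43 CPM. The listed tsRNAs made up only part of that total, and what the rest holds is not given in the sources used here. Intervals and floors made from the recovered reads cover counting error only, since amplified reads are not independent molecules. The median number of reads per tsRNA was alike in libraries of very different totals. The sources used here do not say whether reads were limited, collapsed or sampled before counting, and if they were, the recovered reads and the intervals, floors, ratios and count tests made from them do not have their usual meaning.

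Before the data were examined, the tests, the lists and the rule for naming tsRNAs were fixed for either counts or CPM. Since the table held CPM, the tests for CPM were used, and the alternatives that had been fixed for counts did not apply. The main test was limma (eBayes with trend) on log2(CPM + 1), over the 707 tsRNAs with at least 1 CPM in at least 5 libraries, with all 15 libraries and the 3 groups in 1 model. Fold changes are on this scale, which can understate or overstate the change of low tsRNAs, since libraries at 0 weigh heavily in it. For isoproterenol versus control, tRF-Asn-GTT-022 was at 6.48 on this scale and 8.04 by edgeR on the recovered reads. tRF-Ile-GAT-003 was at -5.47 and -3.72. Benjamini-Hochberg adjusted p-values under 0.05 within a comparison counted as changed, and all tests were two-sided. R 4.3.3, limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0 were used. Since the whole reads could be recovered, edgeR's quasi-likelihood test was also run on them with the authors' totals, over 347 tsRNAs left by its own filter. It called 236 tsRNAs for isoproterenol versus control, 1 for caloric restriction plus isoproterenol versus isoproterenol and 261 for caloric restriction plus isoproterenol versus control.

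Sets were the 53 amino acids and isoacceptors with at least 5 tested members and the 2 classes. They were tested with camera at its preset correlation of 0.01, again with an estimated correlation, and with fry, which asks whether the members of a set move 1 way on balance without setting them against other tsRNAs. Lists fixed as of interest were Gly-GCC, Gly-CCC, Glu-CTC, Glu-TTC, Lys-CTT, Lys-TTT, Val-CAC, Val-AAC, His-GTG, Asp-GTC, Leu-CAG, Ser-GCT, Arg, Met-CAT, Ala and Cys-GCA. Their counts are given over all tsRNAs tested and adjusted over the list alone. Shares of the listed reads were computed for the tiRNA class and the 10 amino acids with most reads and tested by exact permutation of 5 against 5 libraries (252 splits, smallest p 0.0079), with adjustment over the 11 shares.

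The tsRNAs named in a comparison are the 10 that rose and the 10 that fell with the largest absolute log2 fold change among those that passed. Where fewer than 5 passed in a direction, the 5 with the smallest p in that direction were taken. The 10 most abundant tsRNAs over all libraries were added in every comparison, and statements on a set give the members with the smallest p. A ratio against a group with 0 reads was computed against a floor of 3 reads over the group. A ratio against a group with 1 to 3 reads carries its exact 95% counting interval.

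Alternatives changed 1 choice at a time: the scaling, the pseudocount (0.1 or 5 in place of 1), the filter (none, or 10 CPM in place of 1), the test, the samples in the model, the rat number as a block, and leaving out each library. Count tests on the recovered reads, scaling to equal tsRNA totals, thinning all libraries to 106082 reads and the library total as a covariate were added after seeing the data. The main test was run on simulated values of the 707 tsRNAs with 200 changed, in 5 simulations. For isoproterenol versus control it called 5.92%, 40.1% and 80.2% of 2-fold, 4-fold and 8-fold changes, and 2.55% of its calls were false. For caloric restriction plus isoproterenol versus isoproterenol these values were 10.5%, 47.2%, 77.1% and 4.95%. For caloric restriction plus isoproterenol versus control they were 6.29%, 34.6%, 74% and 1.85%. Simulated reads rose in proportion to the library total, and rises and falls were balanced. The recovered reads did not behave so, and these rates may not hold for them. The labels number the animals as separate rats, so the p-values measure the spread between these animals.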

Results

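Fragments of transfer RNAs (tsRNAs) were counted in the left ventricle of 15 rats. The series asks how these fragments differ between rats with and without myocardial ischemia, and with and without caloric restriction. Isoproterenol, a beta-adrenergic agonist that overdrives the heart and injures it, was the means of inducing ischemia. The control group (n = 5) was untreated, the isoproterenol group (n = 5) received the drug, and the restricted group (n = 5) was on caloric restriction before it received the drug. No group was restricted without the drug. An effect of restriction itself therefore cannot be told from an effect on the response to the drug. Library totals as the authors divided them were 273178, 424219, 269508, 1128887 and 381563 reads for control replicates 1 to 5. They were 269399, 127991, 106082, 328607 and 514565 reads in the isoproterenol group and 163818, 397574, 222047, 276329 and 222363 reads in the restricted group. The totals did not differ by exact permutation tests at this n (p = 0.222 for isoproterenol versus control, 0.881 for restricted versus isoproterenol, 0.0952 for restricted versus control).

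The tsRNA pool was dominated by fragments of glycine tRNA. A single fragment, tRF-Gly-GCC-026, held 36.6% of the listed reads averaged over the libraries. It was followed by tRF-Gly-GCC-015 (11.6%), tRF-Gly-GCC-025 (6.45%) and tRF-Gly-GCC-027 (6.17%), and by tiRNA-Ser-GCT-001, of the class cleaved in the anticodon loop (3.4%). This order holds for the average over all 15 libraries and not within groups: tiRNA-Ser-GCT-001 was at 25280 CPM in control, above tRF-Gly-GCC-027 (13530) and tRF-Gly-GCC-025 (8312), but at 1399 and 2930 CPM in the isoproterenol and restricted groups. Listed tsRNAs made up 28.6% ± 4.77 (SD, n = 5) of the library total in control ventricles, 61.6% ± 13.6 in the isoproterenol group and 50.4% ± 13.6 in the restricted group. Both treated groups lay above the control group in every library (exact permutation p = 0.00794 each), and they did not differ from each other by this test (p = 0.222). The number of tsRNAs with at least 1 read was 603.8 ± 10.6 in control, 628.8 ± 12.7 in isoproterenol and 651.2 ± 13.1 in restricted ventricles (exact p = 0.0159, 0.0317 and 0.00794 for isoproterenol versus control, restricted versus isoproterenol and restricted versus control). With at least 5 reads required, the numbers were 367.2, 390.6 and 439.4, and only restricted versus control passed (exact p = 0.349, 0.0714 and 0.00794). The difference in detected tsRNAs between the restricted and isoproterenol groups did not pass without isoproterenol replicate 1, 2 or 3 (exact p = 0.0635 each) or without restricted replicate 2, 3 or 4 (exact p = 0.0556 each).

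**Figure D1:**
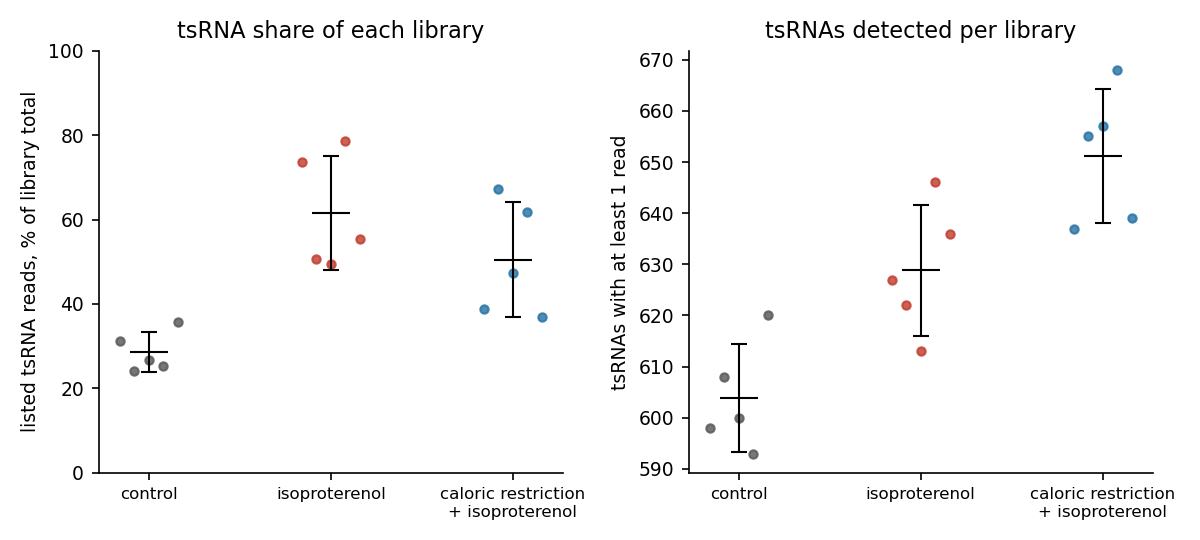
Listed tsRNA reads as a percentage of the library total (left) and tsRNAs with at least 1 read (right), 1 point per library in the control, isoproterenol and caloric restriction plus isoproterenol groups, with the mean ± SD (n = 5). Control libraries lie between 24.2% and 35.7%, isoproterenol libraries between 49.4% and 78.7%; the right axis starts above 0.

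No pair of libraries of 1 group agreed within sampling noise (lowest chi-square per degree of freedom 7.52). Across tsRNAs, Pearson's r between libraries was 0.873 to 0.92 among controls, 0.687 to 0.896 in the isoproterenol group and 0.799 to 0.863 in the restricted group. The first principal component held 50.6% of the variance and placed all 5 control libraries at scores from -58.9 to -30.7, apart from all other libraries (-4.14 to 43.1). Within groups, the level of a typical tsRNA fell with the library total: the median-of-ratios factor of the CPM values and the log2 total, both taken as deviations from their group means over 15 libraries, had a Pearson r of -0.968 and a Spearman rho of -0.968 (permutation p = 2e-05 and 3e-05). Without control replicate 4 and isoproterenol replicate 3, whose totals were farthest from the median, r was -0.958. The median number of reads per tsRNA was 4 to 9 in every library, while the totals spanned a 10.6-fold range.

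**Figure D2:**
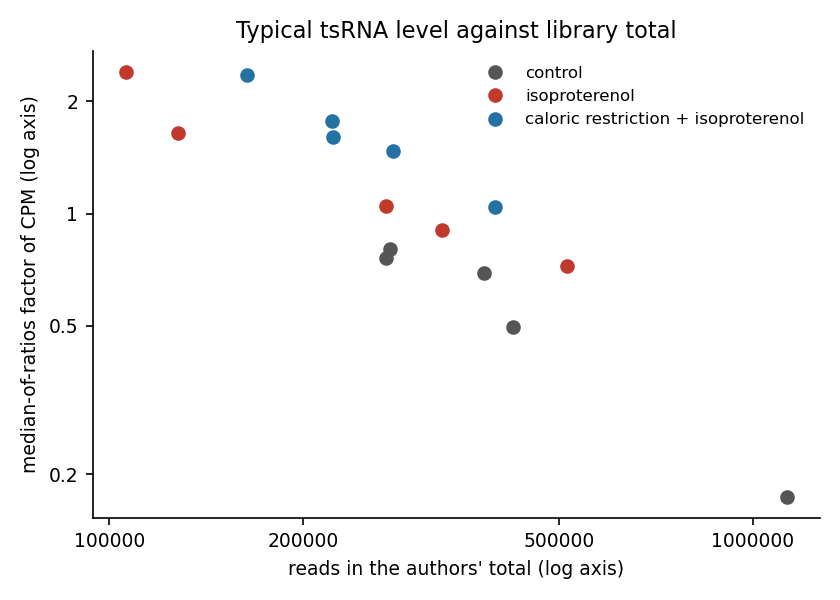
Median-of-ratios factor of the CPM values (vertical, log axis) against the reads in the authors' total (horizontal, log axis), 1 point per library in the control, isoproterenol and caloric restriction plus isoproterenol groups. The factor ranged from 0.174 in the largest library to 2.4 in the smallest.

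Isoproterenol was compared with control to ask what ischemia changed among ventricular tsRNAs. On the log2(CPM + 1) scale the largest rise was that of a histidine fragment. tRF-His-GTG-043 went from 4.27 ± 5 CPM in control to 611 ± 466 CPM in isoproterenol ventricles (n = 5 each), a log2 fold change of 7.29 (SE 0.67, limma adjusted p = 6.26e-12). The rank depends on the scale: by edgeR on the recovered reads it was at 7.285, below tRF-Asn-GTT-022 (8.036) and tRF-Gln-TTG-034 (7.412). A serine tiRNA was the most abundant tsRNA that fell. tiRNA-Ser-GCT-001 went from 25280 ± 15600 to 1399 ± 835 CPM, a log2 fold change of -4.22 (SE 0.51, limma adjusted p = 6.15e-09). Tryptophan tsRNAs went from 5.54% ± 1.57 to 0.536% ± 0.345 of the listed reads (exact permutation p = 0.00794, adjusted p = 0.0175). They were mostly fragments of Trp-TCA, the anticodon of the mitochondrial tryptophan tRNA.

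By limma, 339 of the 707 tsRNAs tested changed, 251 higher and 88 lower (74% higher). The median log2 fold change of all tsRNAs was 1.26 by deposited CPM and 0.15 after median-of-ratios scaling. That scaling takes the typical tsRNA as unchanged and lowered most values here, so falls that stay called under it are no independent support. With that scaling 253 changed, 114 higher and 139 lower (45.1% higher), and 202 of the 339 calls remained in the same direction (114 higher, 88 lower) with 0 in the opposite one. With the listed tsRNAs of each library scaled to the same total, 214 changed, 97 higher and 117 lower (45.3% higher). In 194 tsRNAs (27.4%) the 2 groups did not overlap, against 0.79% by chance.

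The 10 tsRNAs that rose most also included tRF-His-GTG-042 (573 ± 424 against 10.5 ± 11.4 CPM, log2 fold change 5.85), tRF-Val-CAC-023 (1255 ± 1260 against 21.5 ± 16.8 CPM, 5.55) and tRF-Asn-GTT-021 (1713 ± 961 against 47.7 ± 38.9 CPM, 5.42). tRF-Asp-GTC-040 rose by 5.35, tRF-Asp-GTC-039 by 5.28 (1892 ± 1790 against 41.8 ± 26.5 CPM) and tRF-Gly-CCC-009 by 4.93. Relative to the median of all tsRNAs, tRF-His-GTG-043 lay 6.04 higher, tRF-Asn-GTT-021 4.17 and tRF-Asp-GTC-039 4.03. tRF-Asn-GTT-022 averaged 98.4 ± 52.1 CPM in isoproterenol ventricles and had 0 reads in control, at least 66.8-fold higher. tRF-Gly-TCC-050 averaged 42.9 ± 29.5 CPM against 0 reads, at least 27.6-fold higher. tRF-Gln-TTG-034 had 128 reads against 1 in control, a ratio of 235 (95% counting interval 41.5 to 9370).

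The tsRNAs that fell most came from other tRNAs, with 1 exception: His-GTG gave both some of the largest rises and 2 of the largest falls. tRF-Ile-GAT-003 went from 239 ± 75.2 to 14.5 ± 23.2 CPM (log2 fold change -5.47, SE 0.78, limma adjusted p = 2.3e-07), 6.73 below the median of all tsRNAs. By edgeR on the recovered reads its log2 fold change was smaller, at -3.72 (edgeR adjusted p = 1.23e-05). tRF-Lys-TTT-017 went from 186 ± 40.6 to 7.55 ± 6.31 CPM (-4.96), tRF-Pro-TGG-009 from 207 ± 17.6 to 13.5 ± 12.1 CPM (-4.54) and tRF-Ser-GCT-034 from 1745 ± 679 to 114 ± 97.4 CPM (-4.47). tRF-His-GTG-031 (-5.28), tRF-Cys-GCA-046 (-4.55) and tRF-His-GTG-028 (-4.36) fell as well. Reads were few in the isoproterenol libraries for tRF-Ser-GCT-049 (means of 0.777 ± 1.74 and 43.4 ± 5.74 CPM; 2 reads against 110 pooled, 29.9-fold lower, counting interval 8.08 to 250) and tRF-Leu-TAA-047 (1 against 71, 38.6-fold lower, 6.71 to 1550). The 10 largest rises kept their direction and their call when the values were scaled by the median of ratios. These 10 falls did too, which is no test of them, since that scaling lowered most values.

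**Figure D3:**
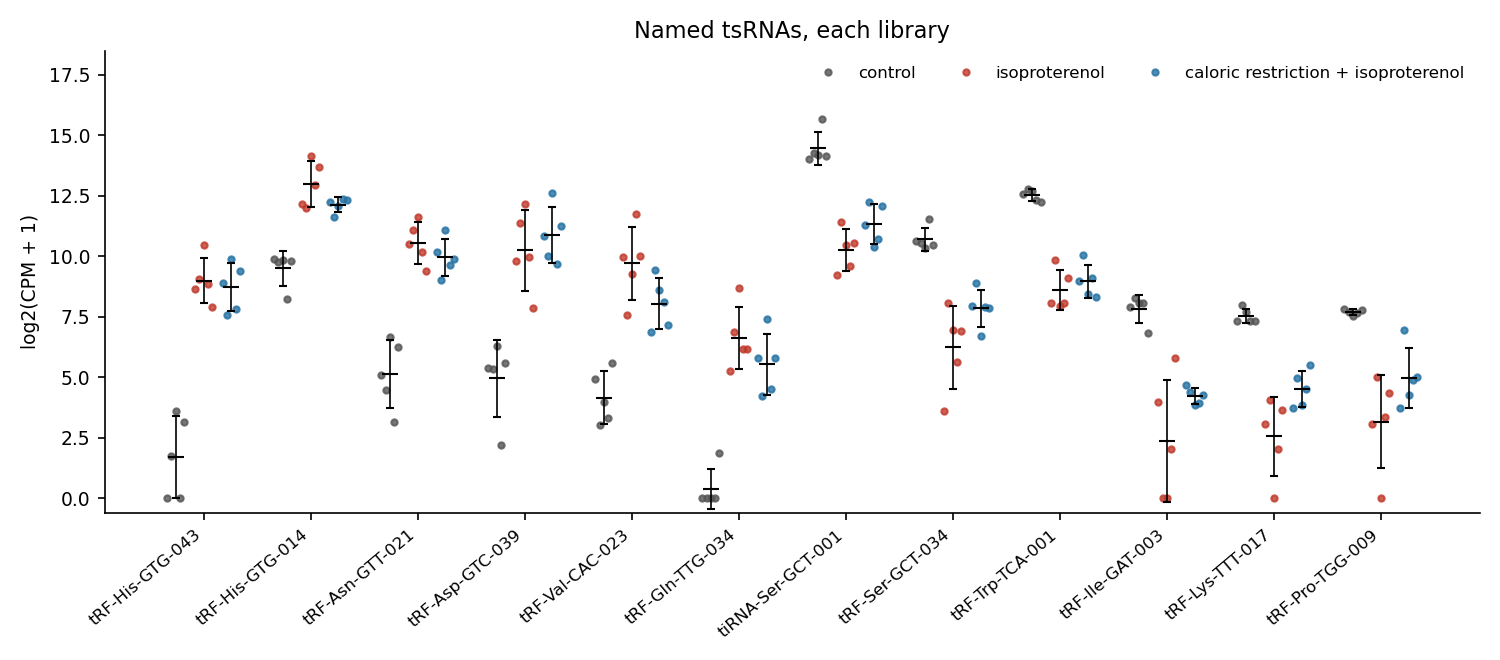
Levels of named tsRNAs as log2(CPM + 1), 1 point per library in the control, isoproterenol and caloric restriction plus isoproterenol groups, with the mean ± SD (n = 5). tRF-His-GTG-043 lies higher and tiRNA-Ser-GCT-001 lower in both treated groups than in control.

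Of the 30 tested members of His-GTG 21 rose and 3 fell (21 and 4 adjusted over the list alone), with a median log2 fold change of 2.76 (1.83 with median-of-ratios scaling). camera placed it above other tsRNAs (adjusted p = 0.0199), a call lost with an estimated correlation (adjusted p = 0.888 with an estimated correlation). The abundant tRF-His-GTG-014 rose from 785 ± 274 to 9658 ± 6150 CPM (3.49, and 2.24 with median-of-ratios scaling). Val-CAC had 15 of 27 members higher and 0 lower (17 and 0 adjusted over the list alone), with a median of 1.74. Its camera adjusted p was 0.0147 (adjusted p = 0.888 with an estimated correlation). Gly-GCC, the parent of the most abundant fragments, had 18 of 35 members higher and 0 lower (18 and 0 adjusted over the list alone; camera adjusted p = 0.0527), and 4 higher with median-of-ratios scaling.

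Within Gly-GCC the 7 most abundant fragments moved unequally. tRF-Gly-GCC-014 rose from 1743 ± 881 to 25980 ± 16900 CPM (3.77, limma adjusted p = 2.33e-07), and by 2.53 with median-of-ratios scaling. tRF-Gly-GCC-025 rose by 2.83, tRF-Gly-GCC-016 by 1.97 and tRF-Gly-GCC-015 by 1.61 as deposited. These 3 rises did not pass with median-of-ratios scaling, at 1.59 (limma adjusted p = 0.0743), 0.73 (0.427) and 0.36 (0.762). tRF-Gly-GCC-026 was at 218900 ± 90300 against 107900 ± 36000 CPM, a log2 fold change of 0.97 that did not pass (limma adjusted p = 0.104) and that turned to -0.28 with that scaling. tRF-Gly-GCC-027 (0.99, adjusted p = 0.101) and tRF-Gly-GCC-023 (0.30, adjusted p = 0.615) did not pass in limma either, and turned to -0.26 and -0.95. edgeR with TMM factors and DESeq2 called the latter lower (-1.37 and -1.25, adjusted p = 0.0334 and 0.0296). Without isoproterenol replicate 4, tRF-Gly-GCC-027 passed (1.37, adjusted p = 0.0233). tRF-Glu-CTC-021 rose by 2.84 (limma adjusted p = 0.000172), but at 1.60 it did not pass with that scaling (adjusted p = 0.0781).

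The other lists with more rises than falls were Glu-TTC (17 of 27 higher, 0 lower; 19 and 0 adjusted over the list alone), Arg (18 of 42 higher, 4 lower; 19 and 4), Ala (19 of 54 higher, 3 lower; 19 and 3) and Leu-CAG (8 of 17 higher, 0 lower; 8 and 0). Lys-CTT had 8 of 18 higher and 1 lower (8 and 1), Asp-GTC 8 of 26 and 4 (8 and 4), Gly-CCC 6 of 19 and 1 (5 and 1), Val-AAC 5 of 10 and 0 (7 and 0), Glu-CTC 5 of 16 and 2 (5 and 2) and Met-CAT 6 of 31 and 2 (1 and 0). With median-of-ratios scaling these counts were 1 higher and 0 lower in Glu-TTC, 11 and 4 in Arg, 5 and 5 in Ala, 2 and 0 in Leu-CAG, 3 and 1 in Lys-CTT, 6 and 6 in Asp-GTC, 1 and 2 in Gly-CCC and 2 and 0 in Val-AAC. The median turned from 0.93 to -0.22 in Glu-CTC and from 0.61 to -0.35 in Met-CAT. None of these 10 lists was called by camera (adjusted p from 0.0832 in Glu-TTC to 0.878 in Asp-GTC).

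Lists with falls were led by Lys-TTT, where 4 of 9 members fell and 0 rose (4 and 0 adjusted over the list alone), with a median of -1.41. Its camera adjusted p was 0.00383 (adjusted p = 0.385 with an estimated correlation). Ser-GCT split: 6 of 19 members rose and 8 fell (6 and 8 adjusted over the list alone). Its median was 0.79 by deposited CPM and -0.09 with median-of-ratios scaling, its mean was -0.47, and camera placed it below other tsRNAs (adjusted p = 0.0203; adjusted p = 0.479 with an estimated correlation). Cys-GCA had 6 of 23 higher and 8 lower (6 and 8 adjusted over the list alone; camera adjusted p = 0.0832). Among all 53 parent sets, camera placed another 6 below the rest. Trp-TCA had 9 of 16 members lower and 2 higher (camera adjusted p = 1.65e-05; adjusted p = 0.247 with an estimated correlation), led by tRF-Trp-TCA-001 (5946 ± 982 to 450 ± 292 CPM, -3.92). The amino acid Trp, which contains it, had 9 of 23 lower and 3 higher (0.00125; adjusted p = 0.385 with an estimated correlation).

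Leu-TAA had 8 of 21 members lower and 2 higher (camera adjusted p = 0.00016; adjusted p = 0.0523 with an estimated correlation), among them tRF-Leu-TAA-025 (1409 ± 717 to 154 ± 71.7 CPM). Pro-TGG had 6 of 13 lower and 0 higher (0.00383; adjusted p = 0.46 with an estimated correlation), with tRF-Pro-TGG-016 from 2245 ± 578 to 420 ± 211 CPM. Ile-GAT had 2 of 6 lower (0.0199; adjusted p = 0.247 with an estimated correlation) and Phe-GAA 3 of 12 lower and 1 higher (0.0421; adjusted p = 0.479 with an estimated correlation). In all, camera called 10 of the 53 parent sets, 2 above and 8 below other tsRNAs, and 7 with median-of-ratios scaling, 1 above and 6 below. fry, which does not set a list against other tsRNAs, called 34, 28 higher and 6 lower. The tRF and tiRNA classes were not called (camera adjusted p = 0.277 for both), with 237 of 658 tRFs higher and 84 lower and 14 of 49 tiRNAs higher and 4 lower.

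**Figure D4:**
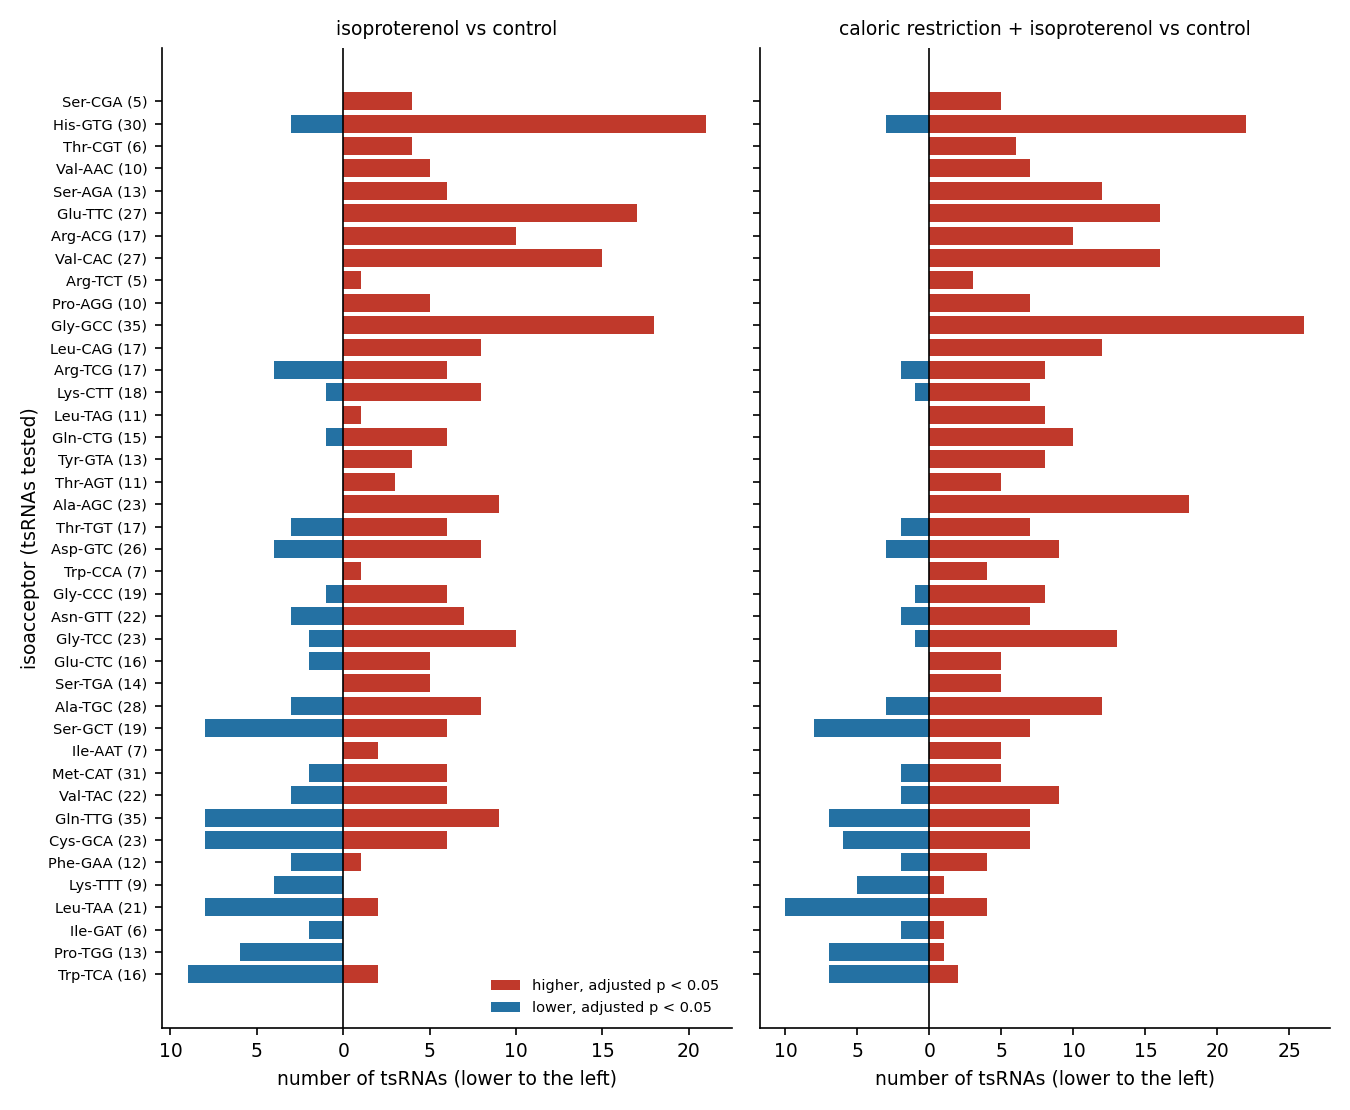
Number of tsRNAs that rose (to the right) or fell (to the left) by limma at an adjusted p of 0.05, for the 2 comparisons with control by deposited CPM. Only isoacceptors with at least 5 tested tsRNAs are shown. His-GTG has 21 rises and 3 falls, and Trp-TCA 2 rises and 9 falls, in isoproterenol versus control.

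Shares of the listed reads, from which the library total cancels as the divisor, moved in 6 of the 11 tested. tiRNAs went from 14.5% ± 6.81 to 4.42% ± 2.01 of the listed reads, serine from 11.8% ± 7.47 to 0.871% ± 0.605 and glutamine from 4.70% ± 1.12 to 1.84% ± 0.769. Histidine went from 0.681% ± 0.189 to 2.98% ± 2.03 (exact permutation p = 0.00794, adjusted p = 0.0175 for these 4 shares) and valine from 1.52% ± 0.441 to 2.75% ± 0.832 (exact p = 0.0159, adjusted p = 0.0291). Glycine, at 60.0% ± 6.96 and 74.7% ± 10.7, did not pass (exact p = 0.0397, adjusted p = 0.0624), but did without isoproterenol replicate 3 (19 points, adjusted p = 0.0291) and without tRF-Gly-GCC-026, the most abundant tsRNA (25.5 points, adjusted p = 0.0291). The histidine difference was 1.5 points without isoproterenol replicate 3 in place of 2.3. This share did not pass without any 1 of the 5 controls (adjusted p up to 0.0698), though the difference stayed at 2.23 to 2.34 points. Nor did the valine share without control replicate 2, 3, 4 or 5 (up to 0.0873, at 1.04 to 1.29 points). Histidine was at 0.3845% to 0.8315% in controls and 1.249% to 6.184% in isoproterenol libraries, so these groups stay apart whichever control is left out. In an exact test of unequal groups, other splits can give as large a difference even where the groups do not overlap. Shares still depended on the total within groups: alanine and arginine fell with its log2 (r = -0.727 and -0.769, permutation p = 5e-05 each, the smallest these permutations can give, adjusted p = 0.000275). With the log2 total in a linear model, chosen after the values were seen, histidine and valine did not pass (1.69 and 0.847 points, adjusted p = 0.155 and 0.103), while glycine did (19.4 points, adjusted p = 0.0355). Without tiRNA-Ser-GCT-001 the tiRNA share differed by -1.51 points, which did not pass (adjusted p = 0.224). The serine share holds the same fragment: in control it was at 25280 CPM, and all Ser-GCT tsRNAs together were at 31490 CPM. The tiRNA and serine falls therefore rest in large part on the same fragment.

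**Figure D5:**
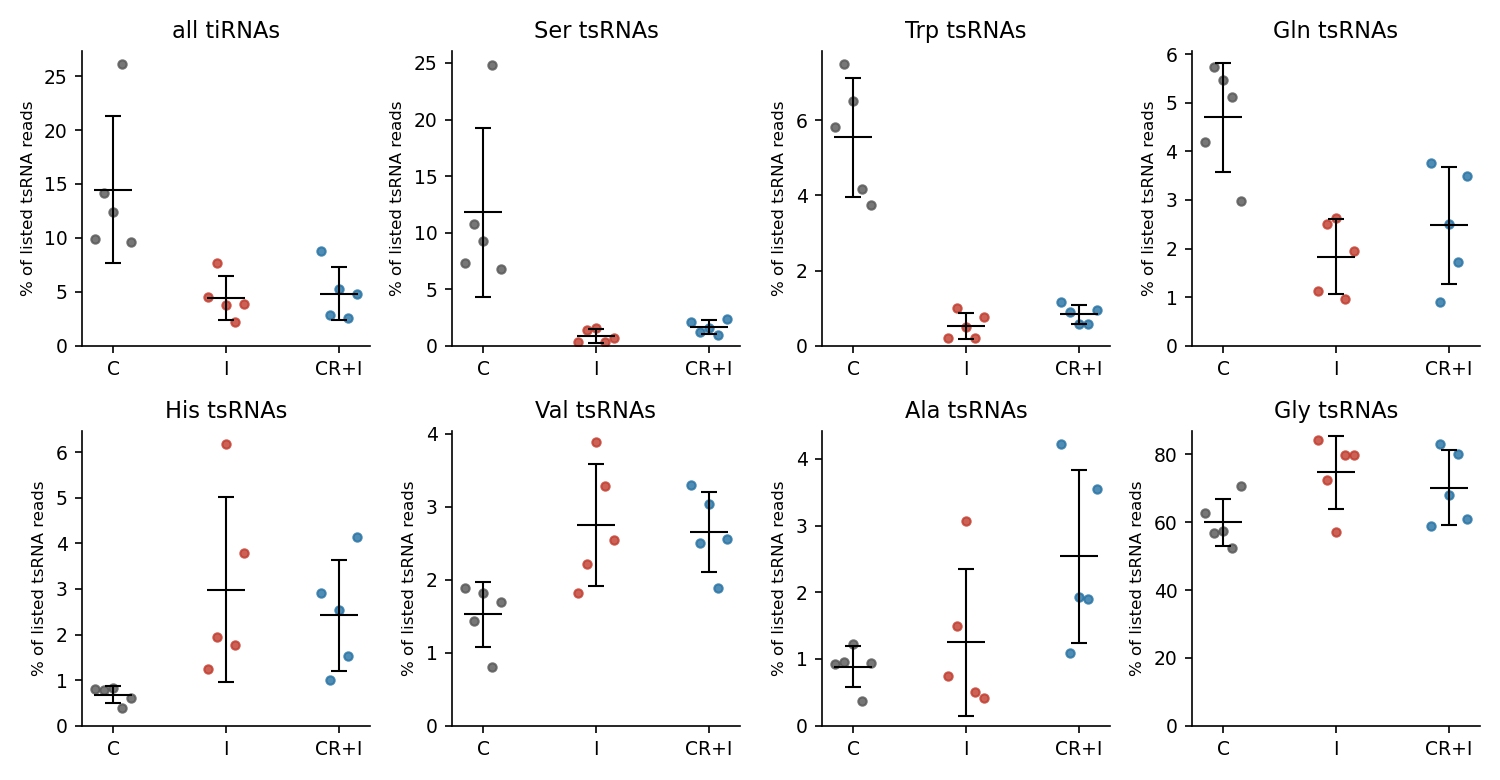
Share of the listed tsRNA reads (percent) in the tiRNA class and in amino acids of the parent tRNA, 1 point per library, for control (C), isoproterenol (I) and caloric restriction plus isoproterenol (CR+I), with the mean ± SD (n = 5). Tryptophan reads lie at 5.54% in control and below 1% on average in both treated groups.

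The title question of the series is what caloric restriction before isoproterenol changed, so the restricted group was compared with the isoproterenol group. By limma, 0 of 707 tsRNAs passed. The smallest adjusted p was 0.204, and 116 tsRNAs had an unadjusted p under 0.05, 78 higher and 38 lower. The tsRNAs with the smallest p were alanine fragments: tRF-Ala-AGC-027 was at 76.2 ± 26.8 CPM in restricted and 12.2 ± 3.21 CPM in isoproterenol ventricles (n = 5 each), a log2 fold change of 2.52 (SE 0.68, limma adjusted p = 0.204). On the lower side, tRF-Gly-GCC-014 was at 6970 ± 4040 against 25980 ± 16900 CPM, a log2 fold change of -1.79 (SE 0.54, limma adjusted p = 0.204). The median log2 fold change was 0.44, 0.10 with median-of-ratios scaling and 0.74 with equal tsRNA totals. Leaving out 1 library moved it both ways, to 0.26 without isoproterenol replicate 5 and 0.63 without isoproterenol replicate 3.

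Other tools gave other counts. edgeR on the recovered reads called 1 tsRNA, tRF-His-GTG-017, lower (log2 fold change -3.27, adjusted p = 0.0414), named here after its value was seen, which in limma was at -0.73 (adjusted p = 0.663). edgeR with TMM factors called 0. Exact permutation tests called 0 as well, but their p cannot go below 0.0079, so a few changes among 707 tsRNAs could not pass. The groups did not overlap in 12 tsRNAs (1.7%, against 0.79% by chance). DESeq2 called 35 of the 449 it tested, 6 higher and 29 lower. These 35 included tRF-Gly-GCC-014 (-2.46, adjusted p = 0.00677) and tRF-Ala-AGC-027 (1.99, adjusted p = 0.00677). With the log2 library total as a covariate limma called 43, 37 higher and 6 lower, among them tRF-Ala-AGC-027 (2.55, adjusted p = 0.0204). DESeq2 on these reads and the covariate were chosen after the values were seen. The unadjusted 95% interval of a typical tsRNA extended 1.52 log2 units (2.86-fold) to either side. In simulated values the test called 10.5% of 2-fold, 47.2% of 4-fold and 77.1% of 8-fold changes in this comparison. Simulated reads followed the library total, unlike the recovered ones, so these rates may not hold here.

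The other tsRNAs named by smallest p, none of which passed in limma without the covariate (adjusted p = 0.204 each), were on the higher side tRF-Ala-TGC-011 (3.45, or 3.01 relative to the median of all tsRNAs), tRF-Phe-GAA-020 (2.41, or 1.97) and tRF-Gly-TCC-018 (2.47, with means of 13.3 ± 5.02 and 3.45 ± 4.76 CPM; 17 reads against 2 pooled, a ratio of 8.93, counting interval 2.12 to 79.7). tRF-Ala-AGC-036 averaged 12.8 ± 11.3 CPM against 0 reads, at least 5.6-fold higher. On the lower side were tRF-Lys-CTT-026 (-2.86), tiRNA-Gln-CTG-002 (-2.53), tRF-Gly-CCC-019 (-2.53) and tiRNA-Gly-CCC-001 (-1.92). With the covariate tRF-Ala-TGC-011 (adjusted p = 0.0405), tRF-Phe-GAA-020 (0.0291), tRF-Gly-TCC-018 (0.041), tiRNA-Gln-CTG-002 (0.0449), tRF-Gly-CCC-019 (0.0377) and tiRNA-Gly-CCC-001 (0.0301) passed. DESeq2 called tRF-Lys-CTT-026 (adjusted p = 0.0493), tiRNA-Gln-CTG-002 (0.00876) and tiRNA-Gly-CCC-001 (0.00876), and the abundant tRF-His-GTG-014 (-1.54, adjusted p = 0.00875). Of the abundant tsRNAs, tiRNA-Ser-GCT-001 was at 2930 ± 1570 against 1399 ± 835 CPM (1.09, limma adjusted p = 0.285). tRF-Gly-GCC-026 (-0.22), tRF-Gly-GCC-015 (-1.06), tRF-Gly-GCC-025 (-0.65), tRF-Gly-GCC-016 (-0.17), tRF-His-GTG-014 (-0.86) and tRF-Glu-CTC-021 (-0.70) had negative values, and tRF-Gly-GCC-027 (0.39) and tRF-Gly-GCC-023 (0.22) positive ones. With equal tsRNA totals the first of these turned to 0.08 and tRF-Gly-GCC-016 to 0.14, and with median-of-ratios scaling tRF-Gly-GCC-023 turned to -0.16.

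camera placed 4 parent sets apart, each lost with an estimated correlation (adjusted p = 0.959 with an estimated correlation for all 4). Ala-AGC lay above other tsRNAs (median 0.98 over 23 members, adjusted p = 0.0419). Lys-CTT (median -0.96 over 18, adjusted p = 0.0288), Glu (median -0.29 over 43, adjusted p = 0.0288) and Val-CAC (median -0.28 over 27, adjusted p = 0.0419) lay below. fry called 0 parent sets. tRFs lay above tiRNAs (median 0.45 and -0.40; camera adjusted p = 0.00907 for each class, adjusted p = 0.283 with an estimated correlation). The number of parent sets was 2 without control replicate 5, without isoproterenol replicate 1 or 3, or without restricted replicate 3 or 4. It was 8 without isoproterenol replicate 5, 9 without restricted replicate 2 and 0 without restricted replicate 5. The classes were not called without isoproterenol replicate 1 or 2.

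Over all tsRNAs tested, 0 members of any fixed list passed in limma. Adjusted over the list alone, Gly-CCC had 2 of 19 higher and 5 lower, Ala 2 of 54 higher and Lys-CTT 1 of 18 lower, and the other 13 lists had 0. The Ala members were tRF-Ala-AGC-027 and tRF-Ala-TGC-011, and the Lys-CTT member tRF-Lys-CTT-026. Of Gly-CCC, tRF-Gly-CCC-014 (2.51) and tRF-Gly-CCC-023 (2.24) were the higher ones, named after their values were seen. No share of listed reads differed (smallest exact permutation p = 0.0317 for lysine, 1.87% ± 0.64 against 2.93% ± 0.544, adjusted p = 0.349; 1 of the 11 shares had an unadjusted p under 0.05).

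No tsRNA passed in limma in isoproterenol versus control and in the opposite direction after restriction, while 50 did at an unadjusted p under 0.05 with a 1.5-fold change, 17 with DESeq2, 10 with the library total as a covariate in limma, 1 with thinned reads and 0 with edgeR. Among the 339 tsRNAs changed by isoproterenol, 57 had an unadjusted p under 0.05 for restriction, 47 of them in the opposite direction and 10 in the same one. tRF-Val-CAC-023 (5.55 for isoproterenol, -1.67 for restriction), tRF-Gly-GCC-014 (3.77, -1.79), tRF-Lys-TTT-017 (-4.96, 1.95) and tRF-Ile-GAT-003 (-5.47, 1.87) were among the opposite ones. The comparisons share the isoproterenol libraries with opposite sign, so opposite values arise by chance. Across tsRNAs, which are not independent replicates, the 2 effects had r = -0.335, against a median of -0.498 (central 95% from -0.756 to -0.111) in simulated unchanged groups. Their covariance was -0.719, against -0.297 (-0.54 to -0.095) in simulated unchanged groups. With the isoproterenol libraries split between the comparisons, the median r was -0.191 (-0.474 to 0.125 over 20 splits).

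The restricted group was compared with control to ask whether treated ventricles of restricted rats differ from untreated ones. On the log2(CPM + 1) scale the largest rise was again that of tRF-His-GTG-043, which was at 503 ± 316 against 4.27 ± 5 CPM (n = 5 each, log2 fold change 7.02, SE 0.67, limma adjusted p = 2.35e-11). This rank holds on that scale only, since tRF-Asn-GTT-022 had no reads in control and its ratio has only a lower bound. tRF-Asp-GTC-039 was at 2475 ± 2210 against 41.8 ± 26.5 CPM (5.92, SE 0.67, limma adjusted p = 2.04e-09). The tryptophan fragment tRF-Trp-TCA-001 fell from 5946 ± 982 to 552 ± 294 CPM (-3.55, SE 0.50, limma adjusted p = 3.06e-07). tiRNA-Ser-GCT-001 fell from 25280 ± 15600 to 2930 ± 1570 CPM (-3.13, SE 0.51, limma adjusted p = 4.1e-06).

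By limma 413 of 707 tsRNAs changed, 337 higher and 76 lower (81.6% higher). The median log2 fold change of all tsRNAs was 1.60 by deposited CPM, 0.24 with median-of-ratios scaling and 1.03 with equal tsRNA totals. With median-of-ratios scaling 253 changed, 107 higher and 146 lower (42.3% higher), and 183 of the calls remained (107 higher, 76 lower) with 0 in the opposite direction. That scaling again lowered most values, so the falls that remained are no independent support. With equal tsRNA totals 275 changed, 175 higher and 100 lower (63.6% higher). In 285 tsRNAs (40.3%) the groups did not overlap, against 0.79% by chance.

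The largest rises included tRF-His-GTG-042 (711 ± 438 against 10.5 ± 11.4 CPM, 6.24), tRF-Asp-GTC-038 (1048 ± 799 against 21.1 ± 11.7 CPM, 5.55), tRF-Gly-GCC-041 (95.5 ± 57.5 against 1.75 ± 3.44 CPM, 5.41) and tRF-Arg-TCG-031 (105 ± 65.4 against 2.39 ± 3.19 CPM, 5.24). Relative to the median of all tsRNAs, tRF-His-GTG-043 lay 5.42 and tRF-Asp-GTC-039 4.32 higher. tRF-Asn-GTT-022 averaged 49.0 ± 33.7 CPM against 0 reads in control, at least 34.1-fold higher. Control ventricles held 1 read each of tRF-His-GTG-041 (5.62, with means of 60.8 ± 27.7 and 0.177 ± 0.396 CPM; against 70 reads pooled, a ratio of 135, counting interval 23.5 to 5420), tRF-Gly-TCC-049 (against 90, 174, 30.4 to 6940) and tRF-Gln-TTG-034 (against 71, 137, 23.8 to 5490). Among the largest falls, tRF-Leu-TAA-019 went from 69.1 ± 16.1 to 3.75 ± 4.17 CPM (-4.46), tRF-Thr-TGT-044 by -4.21, tRF-Ser-GCT-051 by -3.88, tRF-His-GTG-031 by -3.84, tRF-Leu-TAA-003 by -3.80 and tRF-Ile-GAT-003 by -3.61. tRF-Ser-GCT-049 had 1 read against 110 in control (-4.90, with means of 1.22 ± 2.73 and 43.4 ± 5.74 CPM; pooled 56.9-fold lower, 10 to 2270), tRF-Leu-TAA-026 3 against 73 (12.6-fold lower, 4.14 to 62.5) and tRF-Ser-GCT-048 1 against 38 (19.7-fold lower, 3.32 to 797). All 20 kept their direction and their call with median-of-ratios scaling, which is a test of the rises but not of the falls, since it lowered most values.

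His-GTG had 22 of 30 members higher and 3 lower (22 and 3 adjusted over the list alone), with a median of 2.64 (1.26 with median-of-ratios scaling; camera adjusted p = 0.0194, adjusted p = 0.831 with an estimated correlation). Gly-GCC had 26 of 35 higher and 0 lower (27 and 0 adjusted over the list alone), with a median of 2.34 (0.97 with that scaling, 5 higher and 0 lower; camera adjusted p = 0.0295, adjusted p = 0.681 with an estimated correlation). Ala-AGC had 18 of 23 higher and 0 lower (camera adjusted p = 0.0323; adjusted p = 0.831 with an estimated correlation), with tRF-Ala-AGC-053 at 120 ± 50.8 against 5.99 ± 3.92 CPM. The wider Ala list had 33 of 54 higher and 3 lower (33 and 3 adjusted over the list alone), and 13 and 8 with median-of-ratios scaling. Of the abundant Gly-GCC fragments, tRF-Gly-GCC-025 rose by 2.18, tRF-Gly-GCC-014 by 1.98, tRF-Gly-GCC-016 by 1.81 and tRF-Gly-GCC-027 by 1.38 (limma adjusted p = 0.0194). With median-of-ratios scaling none of these 4 passed in limma, at 0.56, 0.35, 0.18 and -0.25. The last also failed without control replicate 2 or without restricted replicate 1 (1.26 and 1.17). tRF-Gly-GCC-026 (0.75), tRF-Gly-GCC-015 (0.55) and tRF-Gly-GCC-023 (0.52) did not pass in limma and turned to -0.88, -1.07 and -1.11. edgeR with TMM factors and DESeq2 called the last lower (adjusted p = 0.0369 and 0.0244). tRF-His-GTG-014 rose by 2.63 and tRF-Glu-CTC-021 by 2.14, at 1.00 and 0.51 with that scaling, where neither passed (limma adjusted p = 0.0888 and 0.571).

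The other fixed lists with more rises than falls were Arg (22 of 42 higher, 2 lower; 22 and 2 adjusted over the list alone), Glu-TTC (16 of 27, 0; 17 and 0), Val-CAC (16 of 27, 0; 16 and 0), Leu-CAG (12 of 17, 0; 12 and 0) and Asp-GTC (9 of 26, 3; 9 and 3). Gly-CCC had 8 of 19 higher and 1 lower (8 and 1), Val-AAC 7 of 10 and 0 (7 and 0), Lys-CTT 7 of 18 and 1 (6 and 1), Glu-CTC 5 of 16 and 0 (3 and 0) and Met-CAT 5 of 31 and 2 (5 and 2). With median-of-ratios scaling the counts were 8 and 5 in Arg, 0 and 3 in Glu-TTC, 3 and 2 in Val-CAC, 4 and 0 in Leu-CAG, 5 and 6 in Asp-GTC and 0 and 1 in Val-AAC. The median turned from 1.16 to -0.40 in Gly-CCC, from 0.74 to -0.36 in Lys-CTT, from 0.81 to -0.54 in Glu-CTC and from 0.45 to -0.87 in Met-CAT. None of these 10 lists was called by camera (adjusted p from 0.123 in Leu-CAG to 0.932 in Asp-GTC).

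Leu-TAA had 10 of 21 members lower and 4 higher (camera adjusted p = 2.93e-05), the 1 set also called with an estimated correlation (adjusted p = 0.0291 with an estimated correlation). Pro-TGG had 7 of 13 lower and 1 higher (camera adjusted p = 2.93e-05; adjusted p = 0.268 with an estimated correlation), with tRF-Pro-TGG-023 from 79.8 ± 17.3 to 8.21 ± 4.65 CPM. Trp-TCA had 7 of 16 lower and 2 higher (0.000297; adjusted p = 0.348 with an estimated correlation), Lys-TTT 5 of 9 lower and 1 higher (6 and 1 adjusted over the list alone; 0.00272; adjusted p = 0.348 with an estimated correlation) and Ile-GAT 2 of 6 lower and 1 higher (0.0347; adjusted p = 0.268 with an estimated correlation). camera also placed Trp (median 0.39, 7 of 23 lower and 6 higher; 0.0194) and Gln-TTG (median 0.50, 7 of 35 lower and 7 higher; 0.0447) below other tsRNAs, although their medians by deposited CPM were above 0. Both medians turned with median-of-ratios scaling, to -0.75 and -1.12 (adjusted p = 0.681 with an estimated correlation for both). Ser-GCT had 7 of 19 higher and 8 lower (9 and 8 adjusted over the list alone; camera adjusted p = 0.0673) and Cys-GCA 7 of 23 higher and 6 lower (7 and 6; 0.149). tRFs (331 of 658 higher, 73 lower) lay above tiRNAs (6 of 49 higher, 3 lower; camera adjusted p = 0.0184 each, adjusted p = 0.331 with an estimated correlation). In all, camera called 10 parent sets, 3 above and 7 below, and fry 44, 39 higher and 5 lower. Without control replicate 1 camera called 6.

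Of the 11 shares of listed reads, 7 differed from control. The tiRNA share was 4.84% ± 2.47 against 14.5% ± 6.81, serine 1.65% ± 0.584 against 11.8% ± 7.47, tryptophan 0.836% ± 0.255 against 5.54% ± 1.57 and histidine 2.42% ± 1.22 against 0.681% ± 0.189 (exact permutation p = 0.00794, adjusted p = 0.0218 each). Valine (2.65% ± 0.546 against 1.52% ± 0.441) and alanine (2.54% ± 1.3 against 0.885% ± 0.309) were higher (exact p = 0.0159, adjusted p = 0.0291 each), and glutamine was lower (2.48% ± 1.2 against 4.70% ± 1.12; exact p = 0.0317, adjusted p = 0.0499). The number of shares was 4, 3 and 2 without control replicate 1, 2 and 4. Histidine and alanine did not pass without control replicate 1, 2 or 4 (adjusted p up to 0.0524 and 0.0624), valine without control replicate 2 or 4 (up to 0.0524), tiRNA without control replicate 4 (0.0524, at -6.69 points), and glutamine without control replicate 1, 2, 3 or 4 or restricted replicate 2, 3 or 4 (up to 0.0873). For histidine and tiRNA the restricted and control libraries did not overlap, so these groups stay apart whichever library is left out. With the log2 library total in a linear model only glutamine and tryptophan passed (-2.58 and -5.02 points, adjusted p = 0.0229 and 9.25e-05). In that model tiRNA (-8.16 points, adjusted p = 0.0521), serine (-7.89, 0.0506), valine (0.798, 0.101), histidine (1.2, 0.238) and alanine (0.927, 0.123) did not pass. Without tiRNA-Ser-GCT-001 the tiRNA share differed by -1.43 points, which did not pass (adjusted p = 0.291). The serine share holds that fragment too, so these falls are not separate results. Arginine and lysine did not pass (adjusted p = 0.0873 and 0.0546), but arginine did without restricted replicate 2 (2.43 points, adjusted p = 0.0349) and lysine without restricted replicate 3 (-1.15 points, adjusted p = 0.0291). Without tRF-Gly-GCC-026 glycine, arginine and lysine passed (15.9, 2.76 and -1.29 points, adjusted p = 0.0194, 0.0194 and 0.0437), and without tiRNA-Ser-GCT-001 lysine passed (-1.15 points, adjusted p = 0.0374).

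Both treated groups differed from control in many of the same tsRNAs: 210 were higher in both comparisons, 65 were lower in both and 0 were opposite. Independent lists of these sizes would share 120 higher and 9.46 lower ones, and simulated unchanged groups against the same controls shared 0. With the controls split between the comparisons the medians were 109 higher (84 to 149) and 35 lower (29 to 40) over 20 splits. Each comparison in a split rests on fewer controls, and the overlap expected for its own lists was not computed. The medians of 109 and 35 therefore cannot be set against 120 and 9.46. Across tsRNAs the log2 fold changes had r = 0.865, against 0.533 in simulated unchanged groups and 0.784 with split controls, and a covariance of 3.492, against 0.297 in the simulations.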

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

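Of the tests in this part, the exchanged groupings, the thinning and the removal of the most abundant tsRNA were fixed before their results, and all others were chosen after the result was seen. A library was singled out when its gap to the nearest other library of its group exceeded 0.71 of the range of that group. Of 192 groups of 5 libraries examined 20 had such a library. Chance flags about 1 in 20 groups of independent normal values, or 9.6. The tsRNAs and shares examined are not independent, and a library with reads is always flagged where the others are at 0. The numbers 20 and 9.6 therefore do not show an excess over chance. Control replicate 4, the largest library, held 9 of the 20. Its total was 1129000 reads against 269500 to 424200 in the other controls. Its tiRNA share was 26.15% against 9.629% to 14.18%, and its serine share 24.85% against 6.812% to 10.74%. tiRNA-Ser-GCT-001 was at 53100 CPM in it against 16440 to 19980 CPM, and tRF-Ser-GCT-034 at 2948 against 1310 to 1567 CPM. tRF-His-GTG-014 was at 297.6 CPM against 867.5 to 937.1, tRF-Asp-GTC-039 at 3.543 against 40.07 to 77.92, and tRF-Asp-GTC-038 at 1.772 against 21.22 to 32.95. tRF-His-GTG-041 had 1 read in it (0.8858 CPM) and 0 in the other controls.

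In control replicate 5, tRF-Ile-GAT-003 was at 112.7 CPM against 237.9 to 308.8 in the other controls. tRF-Gln-TTG-034 (2.621 CPM), tRF-Gly-TCC-049 (2.621 CPM) and tRF-Ala-AGC-036 (7.862 CPM) were present in it and at 0 in the others. tRF-Ser-GCT-049 was at 33.39 CPM in control replicate 3 against 43.93 to 47.17, and tRF-Gly-TCC-018 at 3.661 CPM in control replicate 1 against 20.37 to 30.64. tRF-Gly-GCC-023 was at 9300 CPM in caloric restriction plus isoproterenol replicate 5 against 3513 to 4502. tRF-Ser-GCT-049 was at 3.887 CPM in isoproterenol replicate 5 and at 6.104 CPM in caloric restriction plus isoproterenol replicate 1, with 0 in the other libraries of each group. tRF-Leu-TAA-047 was at 3.712 CPM in isoproterenol replicate 1 and tRF-Ser-GCT-048 at 3.619 CPM in caloric restriction plus isoproterenol replicate 4, also with 0 in the others.

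First, most tsRNAs were higher than control in both treated groups by deposited CPM. With all libraries thinned to the same total (10 thinnings), the median log2 change was 1.367 (1.345 to 1.398) for isoproterenol and 1.767 (1.665 to 1.837) for caloric restriction plus isoproterenol, against 1.26 and 1.60 as deposited, but thinning keeps CPM unchanged on average and cannot remove a dependence on depth, so the bound fixed for it was wrong and it excludes nothing. The most abundant tsRNA, tRF-Gly-GCC-026, is not the cause through the divisor, since its CPM were not lower in the treated groups (log2 changes of 0.97 and 0.75). Taking it out of the totals was therefore bound to raise the medians, to 1.452 and 1.789, and adds nothing to this. Depth and the library total as the divisor stay open: with its log2 in the model the shift of the typical tsRNA was 0.468 (95% interval 0.176 to 0.759) and 0.939 (0.654 to 1.223), intervals that include the bounds set for this test at 0.5 of the shift (0.628 and 0.80), and within groups the level fell with the total at a slope of -0.876 ± 0.069 (SE) per doubling. A change in the amount of tsRNA in treated ventricles may therefore account for part of the shift, but the deposited values cannot separate it from the contents of the total.

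Second, most tsRNAs lower than control carried an anticodon that mitochondrial tRNAs use, 83 of 88 in isoproterenol and 74 of 76 in caloric restriction plus isoproterenol ventricles, a hypothesis found in these data (an anticodon alone does not give the origin). Of all tested tsRNAs with such an anticodon 19.1% and 17% were lower, against 1.84% and 0.735% of the others (Fisher's p = 8.76e-14 and 1.35e-14, with tsRNAs not independent), but more of them were higher by deposited CPM (131 and 163, with median log2 changes of 0.65 and 1.14 against 1.56 and 2.12 for the others), while with median-of-ratios scaling 132 and 131 were lower and 68 and 62 higher, and with equal tsRNA totals 112 and 91 lower and 56 and 94 higher. A factor per library moves both kinds of tsRNA alike, so the authors' normalization by itself cannot make their difference. The median log2 level of tsRNAs with such an anticodon less that of the others differed from control by -1.291 and -1.318 (exact permutation adjusted p = 0.00794 and 0.00794, n = 5). The 2 other scalings gave the same adjusted p, which is no added support, since they leave this gap unchanged apart from the pseudocount. Unequal depth is not the whole cause, since with the log2 total in the model the gap differed by -1.155 (95% interval -1.533 to -0.777) and -1.198 (-1.566 to -0.829), beyond 0.5 of these values (-0.646 and -0.659). Trp-TCA and Ile-GAT, which have 0 nuclear genes in the rat reference table, went from 5.63% ± 1.6 of the listed reads to 0.489% ± 0.337 and 0.751% ± 0.221 (exact permutation p = 0.00794 and 0.00794, adjusted p = 0.0198 and 0.0198, n = 5), which is in line with fewer fragments of these 2 tRNAs and, as a factor per library cannot move a share, not due to the authors' normalization. For the share of listed reads with these anticodons the part of the abundant tiRNA-Ser-GCT-001 stays open: without it the difference was -11.9 points in place of -18.6 for isoproterenol (exact permutation adjusted p = 0.0528 in place of 0.0341) and -7.24 in place of -13.6 for caloric restriction plus isoproterenol (0.202 in place of 0.0528, which did not pass with it either); loss of mitochondria, a change of cell makeup and nuclear copies of mitochondrial genes were not tested.

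The last pattern was that tsRNAs changed by isoproterenol lay mostly in the opposite direction after caloric restriction (47 against 10 among those with an unadjusted p under 0.05). The libraries shared by both comparisons stay open as the cause: the covariance of the effects was -0.719, below the central 95% of 100 simulations of unchanged groups (-0.54 to -0.095, median -0.297), while their correlation of -0.335 lay within it (-0.756 to -0.111, median -0.498). With separate isoproterenol libraries for each comparison it was below 0 in 14 of 20 splits (70%; median -0.482, from -1.078 to 0.39), which could not tell a shift back toward control from chance. For single tsRNAs the answer depended on the test: limma called 0 reversed (50 by unadjusted p and fold), edgeR 0, DESeq2 17 and limma with the library total as a covariate 10.

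The grouping of the libraries was also exchanged, in 100 splits per comparison, with the bound of 5% fixed before the results. For the number of tsRNAs changed, 1 split of 100 was as large for isoproterenol versus control, the real one (339 against at most 162). The same held for caloric restriction plus isoproterenol versus control (413 against at most 224). Both lie below the bound, so chance labels are unlikely to give these numbers. The splits say nothing about a batch or preparation that follows the groups. Chance cannot be excluded for the number of parent sets in the 3 comparisons (10, 4 and 10 against at most 12, 9 and 12, with 6, 14 and 8 splits as large). Nor can it for the classes in the 2 comparisons of caloric restriction plus isoproterenol (2 and 2 against at most 2, with 44 and 36 splits as large). Where limma or camera gave 0, each of the 100 splits is as large by construction, which says nothing about chance. These were the tsRNAs changed for caloric restriction plus isoproterenol versus isoproterenol (highest other 18; 116 by unadjusted p), the classes for isoproterenol versus control (highest other 2) and the reversed tsRNAs (highest other 44).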

How the results depend on the processing

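Among the tsRNAs named, 2209 values under alternatives kept their direction and their status as called or uncalled. Another 35 lost the call, 16 gained it and 42 turned. Among shares these numbers were 425, 48, 9 and 13. The 2209 and 425 are not counts of calls that held, since they include values uncalled in the main test that stayed so. Leaving out each library in turn, also those of the group not compared, gave 435, 280 and 450 of the values of named tsRNAs in the 3 comparisons. The largest rises and falls against control kept direction and call, except tRF-Leu-TAA-026 for caloric restriction plus isoproterenol versus control, which did not pass with thinned reads (-2.40, adjusted p = 0.0931). The abundant Gly-GCC fragments and the counts depended most on the processing. Scaling to equal tsRNA totals, count tests on the recovered reads, thinning and the library total as a covariate were chosen after seeing the data. Few reads limited low tsRNAs, with a median of 4 to 9 reads per tsRNA. Except where the construction is given, the cause was not tested.

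For isoproterenol versus control, 154 tsRNAs changed by edgeR with TMM factors and 214 with equal tsRNA totals, and 273 to 389 leaving out 1 library. The counts for caloric restriction plus isoproterenol versus isoproterenol were 1 with a pseudocount of 5 (tRF-Ala-AGC-027), 1 by edgeR with the authors' totals (tRF-His-GTG-017), 35 by DESeq2, 1 with thinned reads (tRF-Gly-GCC-010, -4.16, adjusted p = 0.0305), 43 with the covariate, 116 by unadjusted p and fold, and 0 leaving out 1 library. Against control, caloric restriction plus isoproterenol gave 253 with median-of-ratios scaling, 261 by edgeR with the authors' totals, 165 with TMM factors, 275 by DESeq2 and 275 with equal tsRNA totals, and 351 to 437 leaving out 1 library. Reversed tsRNAs were 17 by DESeq2, 1 with thinned reads, 10 with the covariate and 50 by unadjusted p and fold.

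With median-of-ratios scaling, edgeR with TMM factors, DESeq2 and equal tsRNA totals, in this order, values for isoproterenol versus control turned to -0.28, -0.175, -0.03 and -0.127 for tRF-Gly-GCC-026, to -0.258, -0.248, -0.11 and -0.104 for tRF-Gly-GCC-027, and to -0.948, -1.371, -1.251 and -0.795 for tRF-Gly-GCC-023, which passed as lower in the count tests among them in both comparisons with control. Values for caloric restriction plus isoproterenol versus control turned to -0.88, -0.53, -0.491 and -0.045 for tRF-Gly-GCC-026, to -1.072, -1.21, -1.178 and -0.237 for tRF-Gly-GCC-015, and to -1.11, -1.335, -1.274 and -0.275 for tRF-Gly-GCC-023. With the first 3 settings tRF-Gly-GCC-027 turned to -0.25, -0.43 and -0.435, and tRF-Gly-GCC-016 turned to -0.246 with TMM factors and -0.266 by DESeq2. In caloric restriction plus isoproterenol versus isoproterenol, equal tsRNA totals gave 0.081 for tRF-Gly-GCC-026 and 0.138 for tRF-Gly-GCC-016, TMM factors and DESeq2 gave -0.182 and -0.325 for tRF-Gly-GCC-027, and median-of-ratios scaling and DESeq2 gave -0.161 and -0.023 for tRF-Gly-GCC-023. Leaving out 1 library gave -0.504 to 0.081 for tRF-Gly-GCC-026, -0.491 to 0.167 for tRF-Gly-GCC-016 and -0.028 to 0.445 for tRF-Gly-GCC-023 in that comparison.

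With an estimated correlation 0, 0 and 1 parent sets were called in the 3 comparisons in the order of the report, and with summed values 41, 0 and 44. The number for caloric restriction plus isoproterenol versus isoproterenol was 7 with median-of-ratios scaling, 1 with equal tsRNA totals, 1 with thinned reads and 2 with the covariate. Leaving out 1 library gave 9 to 12, 0 to 9 and 6 to 10. Of the 2 classes, summed values called 2 for isoproterenol versus control. For caloric restriction plus isoproterenol versus isoproterenol an estimated correlation and summed values called 0, and leaving out 1 library 0 to 2. For caloric restriction plus isoproterenol versus control an estimated correlation called 0. The number of shares was 4 to 7, 0 and 2 to 7 leaving out 1 library.

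Without tiRNA-Ser-GCT-001 the lysine share for isoproterenol versus control turned to -0.098 points, and without the most abundant tsRNA the valine share for caloric restriction plus isoproterenol versus isoproterenol turned to 0.245. With the library total as a covariate Arg and Ala turned to -0.0622 and -0.458 for isoproterenol versus control and Glu to -0.154 for caloric restriction plus isoproterenol versus control, where 2 shares passed in place of 7. Leaving out 1 library, the alanine share ranged from -0.0909 to 0.572 for isoproterenol versus control. For caloric restriction plus isoproterenol versus isoproterenol tiRNA ranged from -0.546 to 1.25, Glu from -1.15 to 0.0939, Val from -0.325 to 0.192 and His from -0.997 to 0.237.

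The rats share only a number between groups: 1 of 15 pairs with the same number had a correlation above 0.1 (-0.119 to 0.253) and 3 of 15 libraries correlated best with their own number. With the number as a replicate block 345, 0 and 421 tsRNAs changed, 9, 2 and 7 parent sets were called, and 0 shares passed in any comparison, since a sign-flip test of 5 pairs cannot give a p under 0.0625.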

Other observations

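Some isoacceptors of the same amino acid had different counts of rises and falls against control. They were chosen after their values were seen, and the difference between them was not tested. In the Leu, Trp, Pro and Lys pairs below, the isoacceptor with mostly falls carries an anticodon that mitochondrial tRNAs use and its partner does not. These pairs are therefore part of the anticodon pattern flagged above and no separate finding. Leu-CAG had 8 of 17 members higher and 0 lower in isoproterenol ventricles, and tRF-Leu-CAG-014 rose from 18.8 ± 14.3 to 391.7 ± 272 CPM (n = 5 each; log2 fold change 4.31, SE 0.61, limma adjusted p = 2.13e-07), while Leu-TAA had 8 of 21 lower and 2 higher. Reads of all Leu-TAA tsRNAs together went from 2386 ± 916 to 556 ± 191 CPM, and those of Leu-CAG from 598 ± 306 to 2078 ± 1270 CPM. Summed Trp-TCA reads went from 15380 ± 3420 to 2650 ± 1550 CPM, while those of Trp-CCA, with 1 of 7 members higher and 0 lower, were at 129 ± 53.8 and 341 ± 295 CPM. Pro-AGG had 5 of 10 higher and 0 lower, with tRF-Pro-AGG-021 at 66.7 ± 28.7 against 8.36 ± 6.58 CPM, while Pro-TGG had 6 of 13 lower and 0 higher. Lys-CTT (8 of 18 higher, 1 lower) and Lys-TTT (0 of 9 higher, 4 lower) were another such pair. Glu-CTC (5 of 16 higher, 2 lower) and Glu-TTC (17 of 27 higher, 0 lower) had more rises than falls alike, as did Val-AAC (5 of 10, 0) and Val-CAC (15 of 27, 0). Glu-TTC carries an anticodon that mitochondrial tRNAs use and had 0 falls. The same held for Ser-TGA (5 of 14 higher, 0 lower), Tyr-GTA (4 of 13, 0) and Leu-TAG (1 of 11, 0).

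Ser-CGA, Thr-CGT and Ser-AGA, also chosen after their values were seen, had many members higher in both treated groups, though camera called none of them. Of all tsRNAs whose anticodon mitochondrial tRNAs do not use, 44.1% and 64% were higher by deposited CPM for isoproterenol and for caloric restriction plus isoproterenol versus control (120 and 174 of 272). With median-of-ratios scaling 46 and 45 were, and with equal tsRNA totals 41 and 81. Ser-CGA had 4 of 5 members higher for isoproterenol versus control and 5 of 5 for caloric restriction plus isoproterenol versus control, with 0 lower (median log2 fold change 2.94 and 3.43, and 1.92 and 2.12 with median-of-ratios scaling; camera adjusted p = 0.118 and 0.0793). tRF-Ser-CGA-015 was at 17.7 ± 13 CPM in control, 150 ± 97.1 CPM in isoproterenol and 195 ± 107 CPM in caloric restriction plus isoproterenol ventricles. Thr-CGT had 4 and 6 of 6 members higher and 0 lower (median 2.09 and 2.87; camera adjusted p = 0.315 and 0.149), with tRF-Thr-CGT-019 at 7.35 ± 8.5, 51.3 ± 56.9 and 71.9 ± 41.5 CPM. Ser-AGA had 6 and 12 of 13 members higher and 0 lower (median 1.81 and 2.54, and 0.99 and 0.98 with that scaling; camera adjusted p = 0.277 and 0.0924), with tRF-Ser-AGA-013 at log2 fold changes of 2.27 and 3.78 (SE 0.62 each).

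The tsRNAs that fell without an anticodon used by mitochondrial tRNAs were few, and are named here after their values were seen. They were tRF-Lys-CTT-020 (-1.40), tRF-Gly-CCC-018 (-2.29), tRF-Gln-CTG-014 (-1.39), tRF-Glu-CTC-014 (-1.40) and tRF-Glu-CTC-018 (-1.20) for isoproterenol versus control, and tRF-Lys-CTT-020 (-1.47) and tRF-Gly-CCC-019 (-2.64) for caloric restriction plus isoproterenol versus control.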
